A study of Mus musculus with 6 samples.

How the data were processed

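Transcripts were measured in 6 libraries of mouse splenic CD8+ T cells stimulated for 48 h, 3 control and 3 DOPAC. Per the labels' protocols, RNA was isolated with TRIzol, cDNA was made full-length with a SMART-Seq HT kit and paired-end libraries with a Nextera XT kit, which do not mark the strand of a transcript. Reads from overlapping and antisense genes cannot be told apart in such libraries. Per the submitters' processing notes, cutadapt 1.9 and HISAT2 2.2.1 were used with the mouse build mm10. The estimator of expression, the annotation release and the filter behind the 11175 listed genes are not given in the sources used here. Groups and replicate numbers came from the library names. One sample title spells the treatment of DOPAC replicate 1 differently, while its library name and treatment label say DOPAC.

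The authors deposited FPKM values per gene and library, per the file headers. The same table holds the authors' log2 fold change, which equalled the difference of mean log2(FPKM + 1) within 1e-06 in all 11175 rows. It also holds the authors' p-values and adjusted p-values, per the file headers, and the headers do not name the test. These were used only where the authors' deposited table is named. All 6 columns of per-sample values were used. FPKM give no read counts, low values showed no steps of whole reads, and the depth of the libraries is unknown. The FPKM sums were 310918, 283818 and 291586 in the controls and 316035, 295549 and 292755 with DOPAC.

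From these values log2(FPKM + 1) was computed, so that a fold change is on that scale and understates the change of genes with low values. Genes with a mean under 1 FPKM over all 6 libraries were left out (288 genes). R 4.3.3 with limma 3.58.1 fitted a linear model with a mean-variance trend to DOPAC against control, with 6.75 total degrees of freedom for each moderated test, and p-values were adjusted by Benjamini and Hochberg over all genes at a threshold of 0.05. Intervals are 95% intervals of that model. Gene lists fixed before the data were examined (35 lists, of which 31 had at least 3 genes above the filter) were tested with limma's camera at an inter-gene correlation of 0.01, which compares a list with all other genes, and adjusted over the 31 lists. With an estimated correlation 0 lists passed (lowest adjusted p 0.449). limma's fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, called 0 lists (lowest adjusted p 0.062). Values per library were compared with exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3 unpaired libraries, or below 0.25 with the pairs of replicate numbers kept. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

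Gene positions and exon lengths came from GENCODE M21 on GRCm38, which held 11067 of the listed genes by identifier and gave a length for 99.2% of the genes tested. Genes were named by a rule fixed before the data were examined. It took the 10 genes with the largest changes per direction among those past the threshold with non-overlapping groups and at least 5 FPKM in the higher group, or, if none passed, the 10 with the smallest p in each direction, which was applied within the same limits on overlap and level. Predicted genes, antigen receptor segments and small RNAs were left out. It added up to 4 genes with the smallest p from each list and 15 fixed genes, of which Nqo1 was not analysed here.

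The replicate numbers are shared by both groups. Deviations from the group means correlated across genes between same-numbered libraries at 0.34, 0.16 and 0.28. Each was above 0.1, and by a rule fixed beforehand the numbers were treated as pairing the samples. The data do not establish this pairing. Deviations within a group balance each other, so these correlations are not independent. Control replicate 2 correlated more with DOPAC replicate 3 (0.24), and DOPAC replicate 2 with control replicate 3 (0.19), than with their own numbers. The labels name no shared animal or day. A fit with the replicate number as a block was an alternative.

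The gene and list tests were tested on simulated data with the means and spread of the 10887 genes. With 200 genes changed and the spread of all 6 libraries, the test recovered 0% at a log2 change of 0.5, 52.5% at 1 and 91.5% at 2. With the spread found without control replicate 1 it recovered 41%, 87.5% and 96.5%. A list moved by 0.5 was called in both settings with 0 other lists called, in simulated noise without correlation between genes. The gene simulation used the same kind of noise, with equal spread in every library. In the data control replicate 1 held 50.6% of the squared deviation from the group means. The recovered percentages therefore need not hold for the real libraries.

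Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, quantile normalization, equal medians, the replicate block, a robust variance model, library weights, 2 rules with a fold minimum, an unmoderated test, an estimated correlation, fry and leaving out each library. Chosen after seeing the data were removal of each library's trend with exon length, alone, with the block and with an estimated correlation, leaving out control replicate 1 with the block or an estimated correlation, lists without shared members, an exact test with the pairs kept and a choice of connective tissue genes without control replicate 1.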

Results

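RNA was sequenced from mouse splenic CD8+ T cells, the cytotoxic lineage of T lymphocytes, that had been activated in culture for 48 h through CD3, the signalling part of the antigen receptor, and the costimulatory receptor CD28. One group of 3 libraries came from cells cultured without further treatment (control) and 1 group of 3 from cells cultured with DOPAC (3,4-dihydroxyphenylacetic acid), a catechol formed when dopamine is broken down. The labels do not say whether the 3 replicates of a group came from separate animals or separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Expression was given as FPKM for 11175 genes, which summed to between 283818 and 316035 per library. FPKM hold no read counts, so the depth of each library is unknown and no counting interval can be given. Of these genes, 10887 had a mean of at least 1 FPKM and were compared. The comparison asked how DOPAC changed the transcriptome of activated CD8+ T cells.

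Genes induced by low oxygen and genes of sugar breakdown were higher in the DOPAC libraries, together with amino acid stress genes. These 3 groups passed the list test at its preset correlation between genes and not with an estimated correlation (adjusted p = 0.449, 0.465 and 0.449). Bnip3, which marks mitochondria for removal, measured 21.4 ± 11.04 FPKM in the controls and 61.1 ± 4.67 FPKM with DOPAC (SD, n = 3 each). Pgk1, an enzyme of glycolysis, measured 531 ± 72.0 and 850 ± 56.9 FPKM (SD, n = 3 each). Asns, the asparagine synthetase gene, measured 17.7 ± 2.50 and 38.0 ± 5.84 FPKM (SD, n = 3 each). In each of these 3 genes all 3 DOPAC libraries lay above all 3 controls. The rule that named the 10 higher genes, these 3 among them, required this separation, so it adds no support.

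No single gene passed the threshold. With limma's moderated test 0 of 10887 genes had a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.801. At an unadjusted p under 0.05 there were 456 genes, 297 higher and 159 lower with DOPAC. As a share of the 10887 genes this lay below the 0.05 that p-values would give with no change. The median log2 fold change of all genes was 0.066, and -0.011 without control replicate 1, so the larger number of higher genes is no sign of induction. The unmoderated test also called 0 genes. The authors' deposited table had 0 genes at an adjusted p under 0.05 and a lowest adjusted p of 0.801. It had 482 genes at an unadjusted p under 0.05, also a share below 0.05. In 1871 genes (17.2%) the groups did not overlap, and 1348 of these were higher with DOPAC. Chance gives 10% on average over the splits of the libraries if all 6 libraries are exchangeable. Where genes move together, the share of any single split can lie far from 10%. The shares of the other splits were not computed, nor was the share with the pairs of replicate numbers kept. An excess over chance can therefore not be read from the 17.2%. The count of genes past the threshold changed without control replicate 1, when 2 genes passed, both lower with DOPAC, and 1574 had an unadjusted p under 0.05. With the replicate block added to that fit 0 genes passed (lowest limma adjusted p 0.132). Of the 2 genes called without the block, 1 was Spp1, the secreted phosphoprotein osteopontin, with a log2 fold change of -3.73 and an adjusted p of 0.030. The other was Gm49510, named because it passed and so chosen after its values were seen (adjusted p = 0.0057), a readthrough-type gene model whose exons overlap Pdxp and Sh3bp1 and which was listed at 0 in all 3 DOPAC libraries and at 0.298, 4.03 and 4.44 FPKM in the controls.

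The 27 hypoxia and HIF-1 target genes, 24 of which were measured above the filter, shifted upward as a group (camera adjusted p = 5.5e-21; adjusted p = 0.449 with an estimated correlation). All 24 had a positive log2 fold change, with a mean of 0.77 ± 0.36 (SD over genes), and 19 passed when adjusted over the list alone, against 0 over all genes. Egln3, an oxygen-sensing prolyl hydroxylase, lies on chromosome 12 at 54178981 to 54203860 (GENCODE M21 on GRCm38, also called mm10) and went from 16.5 ± 5.42 to 40.9 ± 7.71 FPKM (SD, n = 3 each), a log2 fold change of 1.29 (95% interval 0.69 to 1.88). P4ha2, a collagen prolyl hydroxylase subunit, had the value 1.15 (95% interval 0.76 to 1.54) at low levels of 0.373 and 2.05 FPKM. Ndrg1 had a log2 fold change of 1.18 (95% interval 0.61 to 1.75). In the same libraries the macrophage gene Lyz2 had a log2 fold change of -1.93 and the collagen gene Col1a1 of -1.71 (-0.66 without DOPAC replicate 1). The mean over the list was 4.34 ± 0.25 in the controls and 5.11 ± 0.13 with DOPAC on the log2(FPKM + 1) scale (SD, n = 3 each; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 unpaired libraries allow; adjusted 0.269; exact p = 0.25 with the pairs of replicate numbers kept, the smallest that 3 pairs allow).

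Glycolysis genes moved the same way. All 22 listed genes were measured, 21 had positive log2 fold changes, and the mean was 0.51 ± 0.41 (SD over genes; camera adjusted p = 3.4e-13; adjusted p = 0.465 with an estimated correlation). Adjusted over the list alone 13 passed, all higher, against 0 over all genes. The glucose transporter gene Slc2a3 had a log2 fold change of 1.49 (95% interval 0.69 to 2.28) and the lactate exporter gene Slc16a3 of 1.34 (95% interval 0.63 to 2.04). Eno1, which encodes enolase, measured 412 ± 26.0 and 602 ± 35.0 FPKM (SD, n = 3 each), and its reads are uncertain because the near-identical gene Eno1b shares its sequence. Pgk1, on the X chromosome at 106187100 to 106203699, had a log2 fold change of 0.68 (95% interval 0.35 to 1.02). This list shared 6 genes with the hypoxia list. With the shared genes taken out, an alternative chosen after seeing the data, the 18 remaining hypoxia genes averaged 0.83 (adjusted p = 7.3e-16) and the 16 remaining glycolysis genes 0.47 (adjusted p = 3.6e-08).

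**Figure D1:**
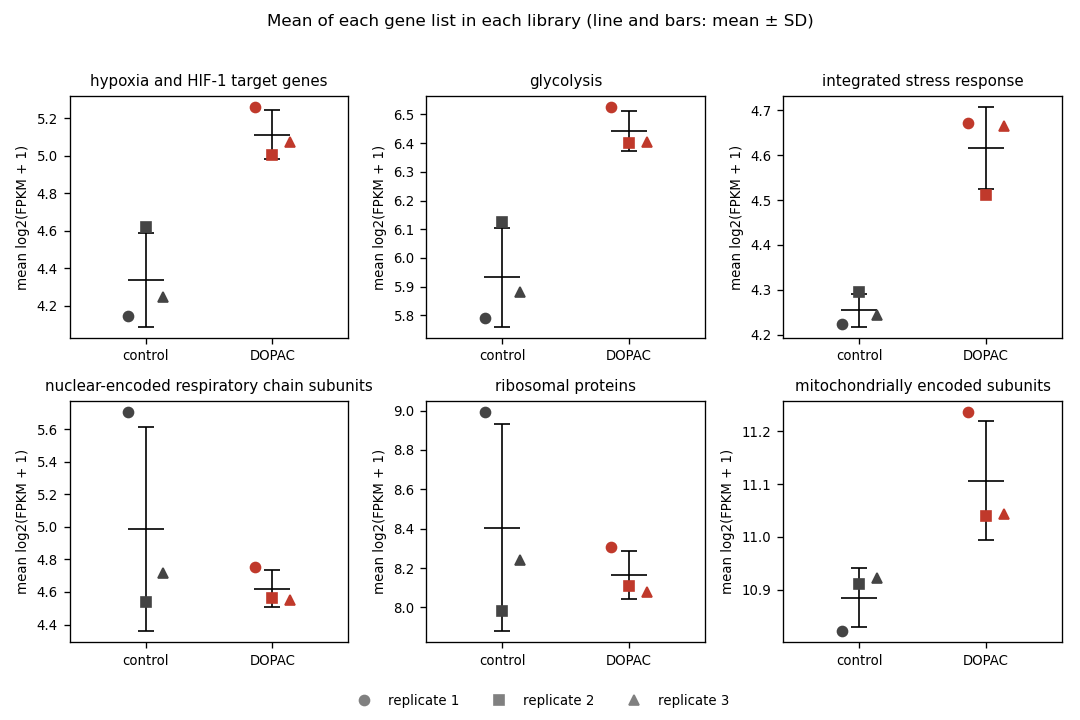
Mean log2(FPKM + 1) of the listed genes in each of the 6 libraries, for 6 gene lists, with control libraries in grey, DOPAC libraries in red, 1 symbol per replicate number and a line and bars for mean ± SD; the vertical axes do not start at 0. For hypoxia genes the 3 DOPAC libraries (5.01 to 5.26) lie above the 3 controls (4.15 to 4.62), while for respiratory chain genes control replicate 1 (5.70) lies above the other 5 libraries (4.54 to 4.75).

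Integrated stress response genes, which cells switch on for example when amino acids run short, were higher as a group (22 of 26 genes measured). Their mean log2 fold change was 0.36 ± 0.34 (SD over genes, camera adjusted p = 8.4e-08, adjusted p = 0.449 with an estimated correlation). Positive values were found for 20, and 6 passed when adjusted over the list alone, against 0 over all genes. That 6 became 11 without control replicate 1 and 3 with the replicate block. Asns, on chromosome 6 at 7675169 to 7693254, had a log2 fold change of 1.06 (95% interval 0.65 to 1.46). Trib3, a pseudokinase gene induced by this pathway, had 0.89 (95% interval 0.50 to 1.29), the transcription factor gene Atf3 1.09 and the alanine aminotransferase gene Gpt2 0.80. Nearby stress lists gave smaller values. The unfolded protein response averaged 0.12 (17 genes, adjusted p = 0.240), with the chaperone gene Hspa5 at 0.33. The heat shock response averaged 0.054 (13 genes, adjusted p = 0.744), with Hsp90aa1 at 0.53. Without control replicate 1 these 2 lists averaged 0.057 and 0.00014, with Hspa5 at 0.19 and Hsp90aa1 at 0.29.

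Among mitophagy receptors and adaptors, Bnip3 and Bnip3l were the 2 of 18 genes that passed when adjusted over the list alone. Bnip3, on chromosome 7 at 138890836 to 138909519, had a log2 fold change of 1.58 (95% interval 0.81 to 2.34), and Bnip3l, on chromosome 14 at 66985239 to 67008877, of 1.27 (95% interval 0.64 to 1.897). Bnip3 was also on the hypoxia list, low oxygen is known to induce both genes, and Bnip3l reads are uncertain because of a near-identical pseudogene. The list as a whole averaged 0.23 (adjusted p = 0.237) and 0.13 without control replicate 1, with Vdac1, a channel of the outer mitochondrial membrane, at 0.27. Without Bnip3 and Bnip3l, an alternative chosen after seeing the data, it averaged 0.075 (adjusted p = 0.798). Autophagy machinery averaged 0.061 over 30 genes (adjusted p = 0.837), with Atg4a at 0.41 and Tfe3 at -0.29, and -0.029 without control replicate 1.

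For targets of NRF2, the transcription factor of the antioxidant response, no shift was detected, with 24 of the 33 listed genes measured. Of 24 measured genes 12 were positive and 12 negative, 0 had an unadjusted p under 0.05, 0 passed when adjusted over the list alone, and the mean was -0.058 ± 0.29 (SD over genes; camera adjusted p = 0.237). Nfe2l2, which encodes NRF2, had a log2 fold change of 0.31 (95% interval -0.12 to 0.74) and Keap1, its repressor, -0.12 (95% interval -0.42 to 0.18). Hmox1, the heme oxygenase gene, had -0.092 (95% interval -0.43 to 0.24), and Gclm, of glutathione synthesis, 0.10 (95% interval -0.42 to 0.62), a sign that flipped with library weights, with the length trend removed and without control replicate 1. Ugdh had 0.41, Srxn1 -0.25 and Ftl1 -0.42. Without control replicate 1 the mean was -0.026, Nfe2l2 had 0.13, Ugdh 0.22 and Ftl1 -0.18. Nqo1 was not analysed here.

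Transcripts of the 13 mitochondrially encoded subunits were higher with DOPAC (12 positive; mean log2 fold change 0.22 ± 0.20, SD over genes; camera adjusted p = 0.0017; adjusted p = 0.640 with an estimated correlation), and quantile normalization ended the call (adjusted p = 0.351). Adjusted over the list alone 0 of the 13 passed. mt-Atp8 measured 3086 ± 435 and 4082 ± 302 FPKM (SD, n = 3 each), mt-Atp6 had a log2 fold change of 0.30, mt-Nd2 of 0.28 and mt-Co1 of 0.33 (0.16 without control replicate 1). Nuclear pseudogene copies of mitochondrial DNA, and the overlap of mt-Atp8 with mt-Atp6, make single values uncertain. The 13 transcripts made up 10.8 ± 1.39% of the summed FPKM in the controls and 12.7 ± 0.491% with DOPAC (SD, n = 3 each; exact permutation p = 0.1, adjusted 0.3).

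The 73 nuclear-encoded respiratory chain subunits and the 42 ribosomal protein genes averaged lower with DOPAC, and both calls ended without control replicate 1. For respiratory chain genes the mean log2 fold change was -0.37 ± 0.32 (SD over genes; 13 positive, 60 negative; camera adjusted p = 6.8e-11; adjusted p = 0.725 with an estimated correlation), and without control replicate 1 it was -0.0063 (adjusted p = 0.902), with a shift against other genes of 0.0075. For ribosomal protein genes it was -0.24 ± 0.23 (camera adjusted p = 2.0e-05; adjusted p = 0.806 with an estimated correlation), and 0.055 without that library (adjusted p = 0.228). Without control replicate 2 the shifts of both lists against other genes were larger, at -0.66 and -0.51 against -0.41 and -0.28 with all 6 libraries. Adjusted over the list alone 0 genes passed in either list. Cox6a1 measured 193 FPKM in control replicate 1 and between 56.2 and 89.2 FPKM in the other 5 libraries. Rpl32 measured 916 FPKM there and between 356 and 434 FPKM elsewhere. Control values of Ndufa5, Atp5g3, Rps19 and Rps20 were 25.0, 123, 92.3 and 116 FPKM in that library and at most 11.5, 68.3, 53.7 and 62.3 FPKM in the others, while Uqcrc2 had a log2 fold change of 0.25 and Rplp2 of -0.66 (-0.39 without that library).

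Control replicate 1 stood apart from the rest. Its correlation with the other 5 libraries over genes (Pearson's r of log2(FPKM + 1), genes not being independent replicates) was 0.899 to 0.917, where those 5 gave 0.974 to 0.992 among themselves. It held 50.6% of the squared deviation from the group means. Genes with a short summed exon length were high in it. For lengths over 500 and up to 1000 bp its median deviation from the other 5 libraries was 0.60 on the log2 scale, and above 8000 bp it was -0.67.

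**Figure D2:**
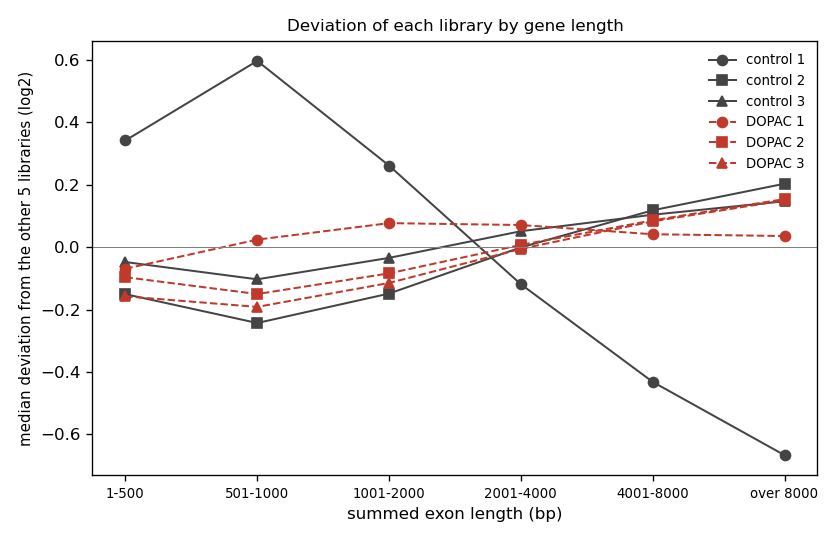
Median deviation (log2) of each library from the mean of the other 5, for genes in 6 ranges of summed exon length in bp; grey lines are control libraries and dashed red lines DOPAC libraries. Control replicate 1 runs from 0.60 at lengths over 500 and up to 1000 bp to -0.67 above 8000 bp, while in that longest range the other 5 libraries lie between 0.035 and 0.20.

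Several cytotoxic genes had higher values with DOPAC, while 12 of the 19 genes of their list had negative log2 fold changes. The list was not called with all 6 libraries. Ifng, which encodes interferon gamma and lies on chromosome 10 at 118441046 to 118445892, measured 80.5 ± 2.16 FPKM in the controls and 140 ± 45.1 FPKM with DOPAC (SD, n = 3 each). Its log2 fold change was 0.74 (95% interval 0.19 to 1.29; limma adjusted p = 0.801), and its exons overlap Gm49751. Prf1, the pore-forming perforin gene, had 0.56 (95% interval 0.15 to 0.96) and Gzmb, the granzyme B gene, 0.55 (95% interval -0.02 to 1.12), with DOPAC replicate 1 at 1248 FPKM and the other DOPAC libraries at 673 and 809 FPKM. Il3 had 0.75 and the chemokine gene Ccl1 -1.01. Without DOPAC replicate 1 Ifng had 0.50, Prf1 0.40, Gzmb 0.30, Il3 0.39 and Il2 -0.18. With all 6 libraries the groups overlapped for Gzmb, Il3 and Il2, and control replicate 1 had 694 FPKM of Gzmb. Tnf had -0.15 (95% interval -0.44 to 0.14) and Il2 -0.42 (95% interval -1.17 to 0.32), or -0.27 without control replicate 1 and -0.72 without DOPAC replicate 3. The 19 effector cytokine and granule genes averaged -0.049 with 7 positive (camera adjusted p = 0.237) and 0.063 without control replicate 1, and 0 passed when adjusted over the list alone, against 2 lower genes without control replicate 1. Without control replicate 2 the list was called lower, with a shift against other genes of -0.21 (adjusted p = 0.024).

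**Figure D3:**
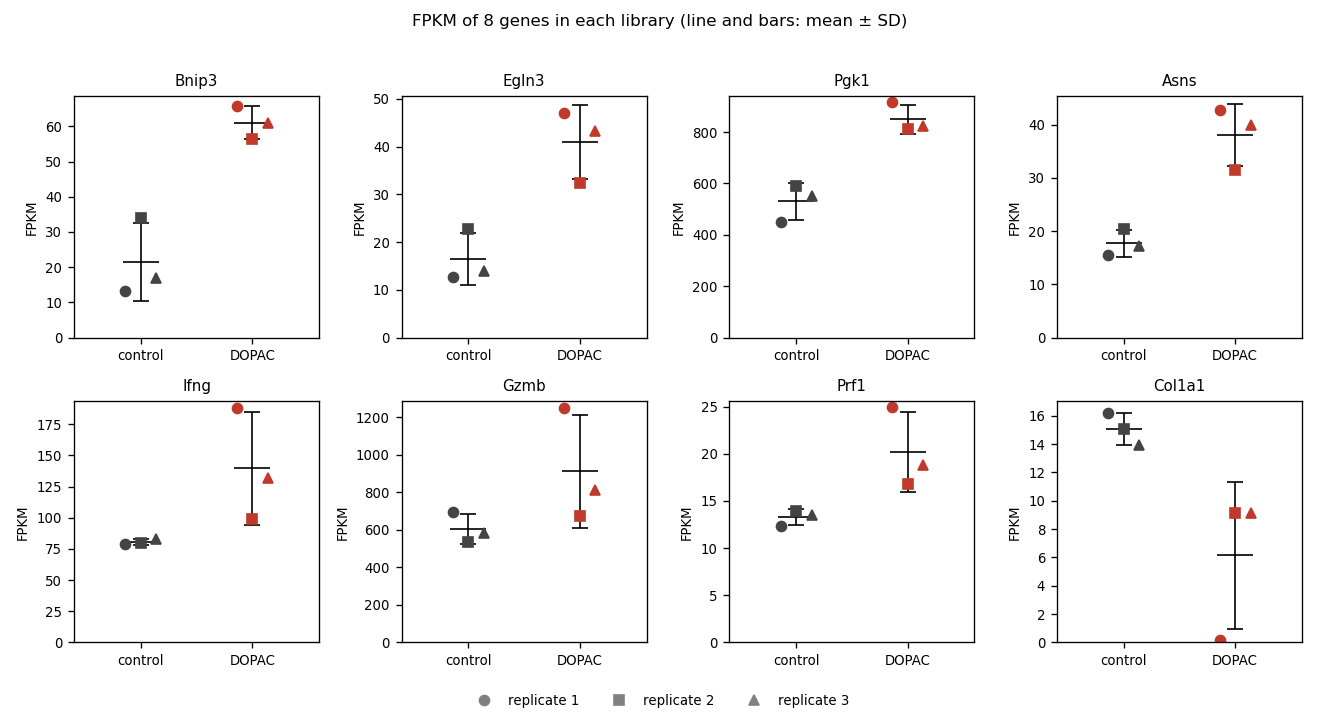
FPKM of 8 genes in the 3 control (grey) and 3 DOPAC (red) libraries, with 1 symbol per replicate number, a line and bars for mean ± SD and axes that start at 0. For Bnip3 the DOPAC libraries lie between 56.4 and 65.8 FPKM and the controls between 13.2 and 33.9 FPKM, and for Col1a1 DOPAC replicate 1 lies at 0.160 FPKM beside 9.12 and 9.16 FPKM in the other DOPAC libraries.

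T cell activation and costimulation genes averaged 0.22 ± 0.23 (SD over 24 genes, 20 positive; camera adjusted p = 0.020; adjusted p = 0.806 with an estimated correlation). Tnfrsf9, the costimulatory receptor 4-1BB, had a log2 fold change of 0.65 (95% interval 0.28 to 1.02), Tnfrsf4 0.51, the transferrin receptor gene Tfrc 0.66 and the interleukin receptor gene Il2rb 0.34. Without control replicate 1 this list averaged 0.10 (adjusted p = 0.221), with Tfrc at 0.26 and Il2rb at 0.17. Without DOPAC replicate 1 Tnfrsf4 had 0.33. Effector differentiation genes averaged 0.27 (13 genes, 12 positive; camera adjusted p = 0.046; adjusted p = 0.806 with an estimated correlation), led by Il12rb2 at 1.05, Klrk1 at 0.62, Klrc1 at 0.47 and Ifngr1 at 0.42. That call was lost with the replicate block (adjusted p = 0.097) and without control replicate 1 (mean 0.11, adjusted p = 0.324; Klrc1 0.31), control replicate 3 (0.095) or DOPAC replicate 1 (0.050; Klrk1 0.40), with quantile normalization (0.061) and with the length trend removed (0.065). In both lists 0 genes passed when adjusted over the list alone. The exons of Il12rb2 overlap Serbp1, so its reads are uncertain. Its log2 fold change was 0.74 without control replicate 1 and 0.78 without DOPAC replicate 1. Inhibitory receptors averaged 0.11 (13 genes, adjusted p = 0.705). Ctla4 had 0.82 (95% interval 0.31 to 1.33), or 0.59 without DOPAC replicate 1. Pdcd1 had -0.035 (95% interval -0.32 to 0.25), a sign that flipped without control replicate 3. Naive and memory genes averaged 0.018 (20 genes, adjusted p = 0.282). Among them Il7r had 0.94, Id3 -0.42 and Tcf7, a transcription factor of naive and memory cells, -0.49 (95% interval -0.98 to 0.01), or -0.32 without control replicate 2. Without control replicate 1 the inhibitory receptors averaged 0.0048, with Pdcd1 at -0.094, and the naive and memory genes -0.090.

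Cell division genes gave no call with the main settings. G2/M and mitosis genes averaged 0.21 (29 genes, 24 positive; camera adjusted p = 0.057; adjusted p = 0.038 with the replicate block and 0.806 with an estimated correlation), with Nusap1 at 0.37 and Cdc20 at -0.31, and without control replicate 1 they averaged 0.027, with Nusap1 at 0.23. Without control replicate 3 or DOPAC replicate 3 that list was called (adjusted p = 0.023 and 0.046), and so it was with no filter (0.048), quantile normalization (0.030), equal medians (0.032) and the length trend removed (0.011). G1/S and DNA replication genes averaged 0.10 (34 genes, adjusted p = 0.282) and -0.014 without that library. The proliferation marker Mki67 measured 58.0 FPKM in control replicate 1 and between 134 and 154 FPKM in the other 5 libraries, so that its log2 fold change of 0.41 (95% interval -0.42 to 1.25) was -0.017 without that library and 0.68 without control replicate 2.

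The remaining lists of metabolism and signalling did not pass with the main settings. Mean log2 fold changes were 0.084 for the tricarboxylic acid cycle (21 genes, adjusted p = 0.392), 0.094 for fatty acid oxidation (18 genes, adjusted p = 0.264; Cpt2 0.39, Eci2 0.30) and 0.10 for mitochondrial biogenesis and dynamics (22 genes, adjusted p = 0.418). Cholesterol synthesis averaged 0.11 (23 genes, adjusted p = 0.438), metallothioneins and metal response 0.28 (6 genes, all positive, adjusted p = 0.277) and iron handling 0.045 (15 genes, adjusted p = 0.744). Interferon-stimulated genes averaged 0.18 (13 genes, adjusted p = 0.216), p53 targets and apoptosis genes 0.037 (21 genes, adjusted p = 0.837; Phlda3 -0.56) and immediate-early genes -0.058 (17 genes, adjusted p = 0.077; Fos -0.61, or -0.38 without DOPAC replicate 1, Dusp1 -0.29). Of the aryl hydrocarbon receptor targets only Tiparp was measured above the filter (0.63, 95% interval 0.18 to 1.09). Without control replicate 1 the means were 0.021 for the tricarboxylic acid cycle, 0.052 for fatty acid oxidation, -0.036 for mitochondrial biogenesis and dynamics and -0.0066 for cholesterol synthesis. They were -0.0079 for iron handling, 0.11 for interferon-stimulated genes, -0.063 for p53 targets and apoptosis genes and -0.023 for immediate-early genes without that library. Metallothioneins and metal response then averaged 0.29 (camera adjusted p = 0.228), with Mt1 at 0.81, Mt2 at 1.05 and Slc30a1 at -0.086. In that fit 2 genes of this list, both higher, passed when adjusted over the list alone, against 0 with all 6 libraries. Leaving out 1 library brought calls for cholesterol synthesis (adjusted p = 0.0013 without DOPAC replicate 1), immediate-early genes (0.0029 without DOPAC replicate 1 and 0.028 without control replicate 3) and interferon-stimulated genes (0.023 without DOPAC replicate 3). Immediate-early genes were also called with no filter (0.048), and cholesterol synthesis with control replicate 1 left out and the replicate block (1.1e-04). For iron handling, p53 targets and naive and memory genes the mean was positive and the direction of the camera test downward.

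Markers of connective tissue and myeloid cells, and 3 genes of the NK and innate-like list, had lower values with DOPAC. B cell markers were not called. The CD8 T cell identity list averaged -0.015 (17 genes, adjusted p = 0.188), with Cd8a at 184 ± 27.3 and 186 ± 7.50 FPKM (SD, n = 3 each), a log2 fold change of 0.023 (95% interval -0.32 to 0.37) whose sign flipped with equal medians, with library weights, with the length trend removed and without control replicate 1 or DOPAC replicate 2. The 5 stromal and endothelial markers averaged -1.19 ± 0.75 (SD over genes; camera adjusted p = 7.6e-04; adjusted p = 0.640 with an estimated correlation), and without control replicate 1 the adjusted p was 0.097 at a mean of -1.20. Without DOPAC replicate 1 the shift against other genes was -0.58, compared with -1.23 for all 6 libraries, and the adjusted p was 2.1e-07. Part of the shift thus came from DOPAC replicate 1. Col1a1 measured 0.160 FPKM there, 9.12 and 9.16 FPKM in the other DOPAC libraries and 14.0 to 16.2 FPKM in the controls. Col1a1, Col1a2, Col3a1 and Sparc had log2 fold changes of -1.71, -1.39, -1.33 and -1.63 (-0.66, -0.61, -0.81 and -0.74 without DOPAC replicate 1). Of the myeloid markers Lyz2, the lysozyme gene of macrophages and granulocytes, measured 21.4 ± 9.58 and 5.32 ± 4.39 FPKM (SD, n = 3 each; log2 fold change -1.93, 95% interval -3.18 to -0.68). In control replicate 1 it measured 11.2 FPKM and in DOPAC replicate 1 10.4 FPKM. Cd68 measured 3.01 and 1.92 FPKM, and with no filter the myeloid list was called lower (adjusted p = 4.0e-06). The NK and innate-like list averaged -0.25 (3 genes; camera adjusted p = 0.020; adjusted p = 0.640 with an estimated correlation; Eomes -0.37, Trdc -0.28, Gata3 -0.10). That call was lost without control replicate 1 (adjusted p = 0.095) or control replicate 2 (0.272; Trdc -0.15). Only these 3 of its 9 genes were measured, and Eomes is also on the naive and memory list. A change of NK cells cannot be read from them. B cell markers averaged -0.043 (3 genes, adjusted p = 0.432; Ighm -0.088) and -0.11 without control replicate 1. The globin genes Hbb-bs and Hba-a1 had -1.30 and -0.77, and -0.84 and -0.35 without control replicate 1, which had 6.72 and 3.69 FPKM.

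Of the 20 genes named by smallest p among those with separate groups and at least 5 FPKM, none passed the threshold. Higher with DOPAC in all 3 libraries were Asns, Trib3, Egln3, Pgk1, Ndrg1, Bnip3, Eno1, Clybl, Bnip3l and Plod2, where Clybl, a mitochondrial lyase gene, had a log2 fold change of 0.63 and Plod2, a collagen lysyl hydroxylase gene, 1.10. Lower in all 3 were Rnasek, Spp1, Hnrnpa3, Lyz2, Timp2, Scamp3, Ms4a4c, Get4, Septin1 and Ctu2. Spp1, on chromosome 5 at 104435118 to 104441050, measured 10.4, 68.8 and 46.1 FPKM in the controls and 2.51, 3.14 and 4.58 FPKM with DOPAC. Hnrnpa3, an RNA-binding protein gene on chromosome 2 at 75659261 to 75669407, measured 27.4 ± 5.29 and 12.8 ± 3.94 FPKM (SD, n = 3 each). Rnasek had -1.19, and its exons overlap Gm21988, so its reads are uncertain. Timp2, a metalloproteinase inhibitor gene, had -0.78, Ms4a4c -0.53, Ctu2 -0.43, Scamp3 -0.39, Get4 -0.38 and Septin1 -0.36, and the exons of Ctu2 overlap Piezo1 and those of Septin1 overlap Zfp553.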

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

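The settings that removed the length trend or combined the loss of control replicate 1 with another change were chosen after seeing the data. The count of genes past the threshold was 0 and became 2 with library weights (both lower) and 45 (21 higher, 24 lower) at an unadjusted p with a 2-fold change. Leaving out each library gave 0 to 2 genes, 0 to 2 lower, and 4 to 12 lists. With no filter 13 lists passed (G2/M, immediate-early and myeloid added), with equal medians 11 (G2/M added), with a filter of 5 FPKM 9 (NK not testable) and with quantile normalization 9 (mitochondrially encoded and effector differentiation lost, G2/M added). With the length trend removed 10 passed (effector differentiation lost, G2/M added) and with the block as well 9 (NK also lost). Of 10 lists past the threshold, 0 passed with an estimated correlation, with or without the length trend and also without control replicate 1, and 0 with fry. Paired by a replicate block, 0 genes and 10 lists passed; the block ended the call of effector differentiation, added G2/M and changed no other call with all 6 libraries, and with control replicate 1 left out 0 genes and 6 lists passed. The median log2 fold change of all genes was 0.066 and at most 0.12, without control replicate 2 or 3. The depth is unknown, so what it limits cannot be given.

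Signs turned in the following cases, and the cause was not tested. Shifts are against other genes, on the log2 scale. With a filter of 5 FPKM they were -0.00056 (autophagy), 0.049 (naive and memory), 0.031 (p53) and -0.0090 (iron), and with quantile normalization 0.00027 (p53). The fold change of Cd8a was -0.035 with equal medians and -0.080 with library weights, where Gclm had -0.081. With the length trend removed, unpaired or in the paired fit with the block, Cd8a had -0.042 and Gclm -0.030; the lists had, also with an estimated correlation, -0.018 (autophagy), 0.033 (effector cytokines), -0.021 (iron) and 0.013 (B cell). With control replicate 1 left out and an estimated correlation they had -0.015 (autophagy), 0.0075 (respiratory chain), -0.022 (mitochondrial biogenesis), 0.077 (effector cytokines), -0.00041 (G1/S), 0.069 (ribosomal) and 0.0038 (CD8 identity). With it left out and the replicate block, Cd8a had -0.11 and Gclm -0.13, and the lists -0.0035 (autophagy), 0.015 (effector cytokines), -0.0025 (iron) and 0.0062 (ribosomal).

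Over fits that left out 1 library the ranges were -0.19 to 0.0050 (B cell), -0.094 to 0.0038 (CD8 identity), -0.00041 to 0.099 (G1/S), -0.015 to 0.047 (autophagy), -0.21 to 0.077 (effector cytokines), -0.011 to 0.043 (heat shock), -0.0018 to 0.011 (iron), -0.022 to 0.12 (mitochondrial biogenesis), -0.076 to 0.038 (naive and memory), -0.66 to 0.0075 (respiratory chain), -0.049 to 0.023 (p53) and -0.51 to 0.069 (ribosomal). The fold changes ranged over -0.10 to 0.095 (Cd8a), -0.14 to 0.24 (Gclm), -0.017 to 0.68 (Mki67) and -0.094 to 0.026 (Pdcd1).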

Other observations

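Connective tissue transcripts were present in these T cell libraries and nearly absent from 1 of them. Taking genes with at least 2 FPKM in every control and under 10% of the control mean in DOPAC replicate 1, a choice made after seeing the data, gave 26 genes. Among them were the collagen genes Col1a1, Col1a2, Col3a1, Col5a1 and the cartilage collagen gene Col2a1, the matrix genes Fn1, Thbs1 and Bgn and the fetal transcript H19. Over the 26 genes the median was 2.22% of the control mean in DOPAC replicate 1, 54.0% in replicate 2 and 56.9% in replicate 3. Gm14303, Rpph1 and Sparcl1 passed only through control replicate 1 (175, 70.2 and 12.3 FPKM there), and Spp1 was low in all 3 DOPAC libraries. Chosen with that library left out, 25 genes (23 of the 26, with Mgp and Gm49510) had medians of 2.03%, 57.5% and 60.0%. Requiring at least 1 FPKM in the other 5 libraries and under 10% of their mean in the library itself, 32 genes were low in DOPAC replicate 1 and 2 to 9 in each of the other 5. The class II gene H2-Ab1, also chosen after its values were seen, went the other way, with 0.720 ± 0.261 FPKM in the controls and 2.27 ± 0.585 FPKM with DOPAC (SD, n = 3 each; limma adjusted p = 0.801).

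The tests of the patterns below were chosen after the results were seen, except the counts of other splits. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. All 10 gave at least the 0 genes of the real split, and the highest other split also gave 0. For gene lists the real split gave 10 and the highest other split 8, and 1 of the 10 splits, the real one, gave as many. With the replicate numbers treated as pairs, which the data do not establish, the real split compares with the 3 others that also part all 3 pairs. These gave 5 to 6 lists.

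For the connective tissue genes a candidate source is RNA from outside the T cells, from 1 origin and in different amounts per library. It would keep their proportions fixed, which the ratios could not decide. Of the 26 genes 80.8% had a ratio of DOPAC replicate 2 to the controls within 1.5-fold of their median ratio. Of all tested genes 89.4% did so around their own median. These shares were 88% and 95.8% with control replicate 1 left out. Most tested genes met this window, so meeting it does not set a single origin apart. The genes outside were Gm14303, Rpph1 and Sparcl1, chosen only through control replicate 1, with Timp3 and Spp1. With that library left out they were Spp1, Mgp and Gm49510. The source stays open. DOPAC treatment does not account for the loss in replicate 1, since replicate 2 of the same treatment had a median of 39.5 times its level over Col1a1, Col1a2, Col3a1 and Sparc, while the lower level of replicates 2 and 3 against the controls stays open. The same origin does not account for Lyz2 and Apoe, which were higher in DOPAC replicate 1 than in replicate 2, by at least 3.26 times.

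Lower respiratory chain and ribosomal protein genes may reflect control replicate 1 alone. Without that library the shifts of the 2 lists were 0.0075 and 0.069. With each library's trend with summed exon length removed, the shifts were -0.32 and -0.21, against -0.41 and -0.28 before. At the preset correlation between genes the camera adjusted p was 4.9e-05 and 0.022 (0.766 and 0.871 with an estimated correlation, where neither list had a call before either). Summed exon length counts every annotated exon and can exceed transcript length. Rps19 had 4685 bp and Rps20 4080 bp on this measure. A bias by transcript length is therefore not excluded. An effect of DOPAC hidden by the spread cannot be told apart from none: in 2 of the 6 pairings with control replicates 2 and 3 the DOPAC library was lower, for either list. What set that library apart was not tested.

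Higher hypoxia and glycolysis genes did not rest on control replicate 1, since the shift was 0.69 for the hypoxia list and 0.45 for the glycolysis list without it. Nor did they rest on the trend with summed exon length, since the shifts were 0.74 and 0.45 with that trend removed. DOPAC itself and a difference in oxygen or cell density between the wells cannot be told apart, because neither oxygen nor density is recorded. The exact permutation p of the hypoxia list was 0.1, the smallest that unpaired libraries allow, and 0.25 with the pairs of replicate numbers kept, the smallest that 3 pairs allow. The list calls also depend on the preset correlation between genes.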
